A study of Homo sapiens with 22 samples.

How the data were processed

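Spatial gene expression was analysed in sections of 22 primary muscle-invasive bladder carcinomas, 1 section per patient. The tissue had been fixed in formalin and embedded in paraffin. The assay was Visium CytAssist: probe pairs against human transcripts are hybridised to the section, ligated, and captured on a slide that carries a grid of barcoded spots. A spot covers a small region that can hold several cells of different types.

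For each tumour the authors deposited a matrix of raw UMI counts per gene and spot, the list of genes, the list of spot barcodes and a table of spot positions. A UMI (unique molecular identifier) count is the number of captured molecules assigned to a gene. The count values were whole numbers with totals that differed between tumours, and no normalization had been applied to them. Space Ranger 2.1.0, R 4.3.1, Seurat 5.1.0 and the genome build GRCh38 are named in the submitters' processing notes, which give no role for any of them. Further settings are not given in the sources used here. The deposited matrices held only spots marked as lying over tissue, as a match of barcodes to the position tables showed for every tumour. All 18085 genes of the matrix were used, named by the symbols that the gene list pairs with Ensembl identifiers; 3 symbols occurred more than once. Gene coordinates were not used here.

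The files held a total of 421355462 UMIs, from 1072554 to 52740499 per tumour. Spots with at least 500 UMIs were kept, 72437 of the 103011 spots over tissue and 253 to 8091 per tumour. In 3 tumours (3, 20 and 22) the median spot over tissue held fewer than 200 UMIs. Each tumour's most similar other tumour was sought to find a section deposited more than once. The highest correlation of log2 CPM (counts per 1000000 UMIs) between any pair of tumours was 0.957, and the median pair had 0.819. The position tables showed 2 slide formats, a grid of 14336 spots (8 tumours, called the large format) and a grid of 4992 spots (14 tumours, the small format). Slide format was treated as a technical batch. All tumours form a single group in the labels, so no comparison between groups of tumours was made.

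Gene lists, score rules, tests, the rule for named genes and a first set of other settings were fixed before the data were examined. The lists came from textbook markers, not from these samples. Of 356 genes in the lists, 19 were not analysed here because the gene list held no such symbol, among them KRT18, CD8B, the tryptase genes TPSAB1 and TPSB2, and 7 genes of the MHC class II list. That list was left with CD74 alone and was not tested. A total of 16 genes, XIST and Y-linked genes, were left out of every test.

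Classes of spots were made within each tumour. For every spot, the mean of log2(UMIs per 10000 + 1) over stromal genes was subtracted from that over epithelial genes. Spots above the tumour's median of this difference are called its epithelial side, and the others its stromal side. Epithelial-high and stromal-high spots were the top and bottom 25% of all spots. Within the epithelial side, luminal-high and basal-high spots were the top and bottom 25% by the luminal minus the basal list; tied values at a threshold stayed together. Within the stromal side, B-cell-high spots were the top 10% by UMIs of the B-cell list per 10000 that also held at least 3 such UMIs. Each comparison left out the genes of the lists that defined its classes. Tumours with fewer than 20 spots in a class were left out, which removed none from the first and second comparisons and 6 (tumours 6, 9, 12, 18, 19 and 20) from the B-cell comparison. A class made from a score is a range and not a cell type. A median of 13.3% of spots per tumour lay within 0.1 SD of a threshold of the epithelial minus stromal score, 16.4% for the luminal minus basal score and 1.99% for the B-cell score.

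UMI counts were summed per tumour and class and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, the quasi-likelihood test with the tumour as a block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The pairing comes from the tissue itself, since both classes lie in the same section. Errors of log2 fold changes are standard errors. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 29 lists. The number of list members past the threshold is given over all genes tested and, where it differs, adjusted over the list alone. Levels of single genes are means over tumours of TMM-scaled CPM. Named genes were drawn from the 6 with the largest change in each direction that had an adjusted p under 0.05, the same direction in at least 80% of tumours and at least 10 CPM in the higher class. Up to 3 members with the smallest adjusted p were named per list that passed, up to 2 for lists named without passing, and further genes came from a fixed set of drug targets and immune genes, whatever their values.

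Distance was counted in steps on the hexagonal grid from each spot of the stromal side to the nearest B-cell-high spot. Summed list CPM, with a pseudocount of 1, were compared on the log2 scale at 1, 2 and 3 steps with 6 or more steps in the same tumour, by an exact two-sided sign-flip permutation test over 16 tumours, adjusted over 30 values. Correlations across the 22 tumours used log2(CPM + 1) of TMM-scaled sums and two-sided permutation tests with 100000 resamples for 16 pairs of measures. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

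The steps were tested on simulated counts with known changes in 200 genes per comparison. Of the genes changed 1.5-fold, 2-fold and 4-fold, the epithelial against stromal test recovered 50.0%, 96.7% and 100.0% with 3 false calls among 17839 genes. The luminal against basal test recovered 10.1%, 51.7% and 100.0% with 4 false calls among 17382 genes. The B-cell test recovered 9.46%, 79.2% and 100.0% with 9 false calls among 13626 genes. These false calls are from simulated counts in which no other genes changed between classes. They do not give a rate of false calls in the tumours. The distance test made 0 of 30 calls with random spots in place of B-cell-high spots, though mean log2 differences there reached 0.73 in size. These spots were scattered over the stromal side. The check therefore does not cover a silent-gene level that differs around the real B-cell-high spots.

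Background was measured after the data were seen. A set of 348 olfactory receptor genes, which are silent outside sensory tissue with few exceptions, gave a silent-gene level per spot, expressed as a percent of an even share. An even share is the level every gene would have if all UMIs were spread evenly, 55.3 CPM. A second set of 39 taste receptor, vomeronasal receptor and defensin genes was used to check it. Low-background spots are those with a silent-gene level under 25%. The silent-gene shift of each comparison is given beside the gene groups it moves with. In the luminal against basal test 180 of 307 silent genes were called lower in luminal-high spots. The simulated counts held no such shift.

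Other settings fixed in advance were DESeq2 1.42.0, library size only, no filter on low counts, no tumour block, UMI minimums of 200 and 1000, other class sizes, spots thinned to 500 UMIs, 1 log2 ratio per tumour with limma, each slide format alone, and, for distance and correlations, other pseudocounts, references and summaries. Added after seeing the data were low-background spots, low-background spots within each slide format, all tumours but the 3 shallow ones, a test of the class difference between slide formats, distances tested as CPM differences with and without subtraction of the silent-gene level, and ranks adjusted for background. Lists were also set against 10000 random lists matched on expression.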

Results

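Spatial transcriptomes of 22 muscle-invasive bladder carcinomas were collected to describe tumour lineages, drug targets and the organisation of immune cells in the tissue. Each tumour gave 1 section, and the sample labels place all tumours in a single group, so groups that the labels do not name could not be separated. The sections held 103011 spots over tissue and 421355462 UMIs in 18085 genes, with 1072554 to 52740499 UMIs per tumour. After a minimum of 500 UMIs, 72437 spots remained, with a median of 1062 to 16104 UMIs and 864 to 6427 detected genes per spot in the different tumours. The 8 tumours on the large slide format had median depths of 1062 to 3647 UMIs per kept spot, and the 14 on the small format 1521 to 16104.

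Olfactory receptor genes, which are silent outside sensory tissue with few known exceptions, had a mean level of 20.6% ± 20.6 (SD, n = 22) of an even share of the UMIs. The tumours ranged from 1.89% to 87.6%. A second set of silent genes gave a mean of 20.7%. The level moved with depth: in the shallowest 20% of spots of a tumour it had a median over tumours of 43.0%, and in the deepest 20% a median of 4.93%. This silent-gene level is the background against which low genes have to be read.

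**Figure D1:**
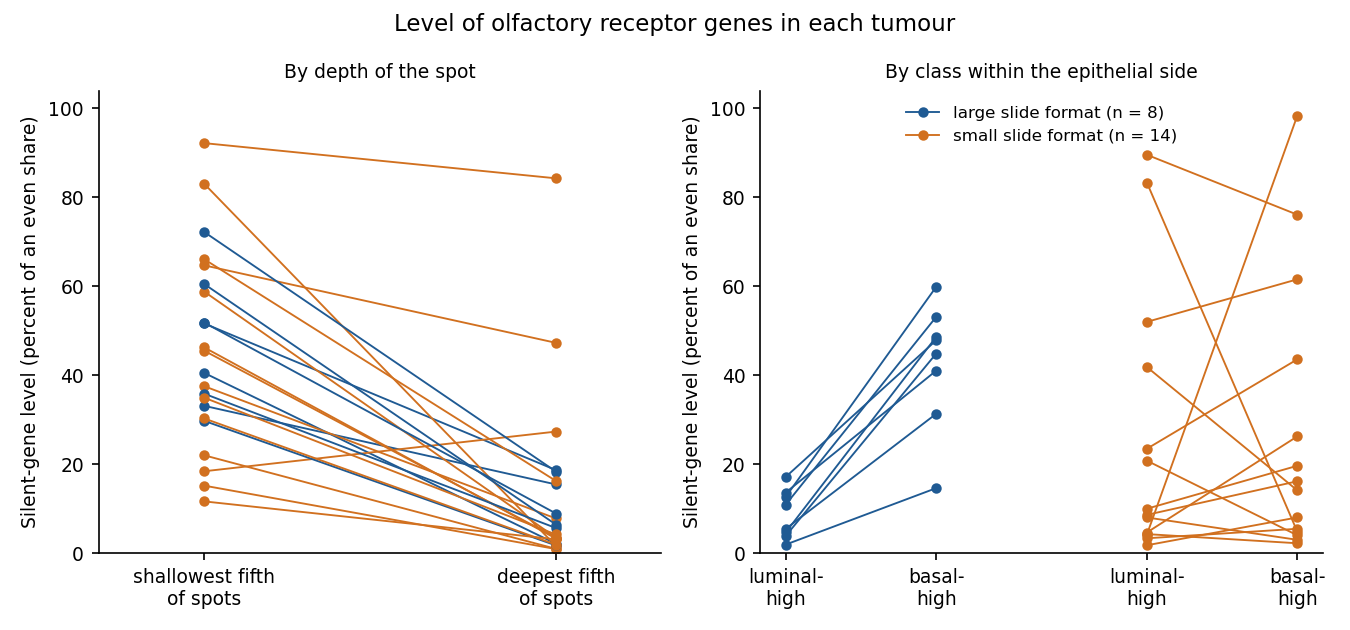
Silent-gene level of each tumour, as a percent of an even share of UMIs, by depth of the spot (left) and by class within the epithelial side (right), with 1 line per tumour coloured by slide format. Basal-high spots lay above luminal-high spots in 8 of 8 tumours of the large format and in 8 of 14 of the small format.

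The first comparison asked what epithelial-high spots express against stromal-high spots of the same tumour, beyond the keratin, adhesion and collagen genes that defined them. Epithelial genes had medians over tumours of 66.4 and 4.06 UMIs per 10000 in the 2 classes. The classes are ranges within a tumour and not carcinoma against stroma in each. In tumour 8 the epithelial medians were 15.7 and 60.5, and in tumour 9 stromal-high spots had a stromal median of 0. ANXA9, an annexin, was 7.49-fold higher in epithelial-high spots (log2 2.90 ± 0.35, n = 22), and S100P, a calcium-binding protein, was 6.73-fold higher (2.75 ± 0.43). The surface antigen PSCA was 5.97-fold higher, in 20 of 22 tumours. The mucosal chemokine CXCL17 rose 5.73-fold and the oxidoreductase DHRS2 5.54-fold. The muscle filament gene DES was 18.1-fold lower in epithelial-high spots (log2 -4.18 ± 0.54) and calponin, CNN1, 15.3-fold lower (-3.93 ± 0.36). The Wnt modulator SFRP2 (14.4-fold), periostin, POSTN (14.1-fold), smooth-muscle actin, ACTA2 (13.8-fold), and the BMP antagonist GREM1 (13.6-fold) followed, each lower in at least 21 of 22 tumours.

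Of 17856 genes tested, 4886 were higher in epithelial-high spots and 3008 lower. The comparison used 18119 epithelial-high and 18120 stromal-high spots, with 64 to 2023 per class and tumour. Of 29 gene lists, 24 passed the list test, 7 higher and 17 lower; with an estimated correlation none did, and the lowest adjusted p was 0.0606. Silent genes had a level of 16.5% in epithelial-high and 20.7% in stromal-high spots, and 8 of the 341 tested were lower in epithelial-high spots.

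Further luminal genes rose in epithelial-high spots. Of 13 tested 12 were higher (adjusted p = 4.25e-08; adjusted p = 0.0606 with an estimated correlation), among them GRHL3, a transcription factor of umbrella-cell differentiation, 4.17-fold. Of 14 further basal genes 8 were higher and 2 lower, or 9 and 2 adjusted over the list alone (adjusted p = 0.0429; adjusted p = 0.453 with an estimated correlation). TRIM29 (3.25-fold) and the basal transcription factor TP63 (2.97-fold) were higher, whereas podoplanin, PDPN, which fibroblasts and lymphatic vessels also make, was 6.43-fold lower, in 22 of 22 tumours. Of 17 squamous genes 11 were higher, or 12 adjusted over the list alone (adjusted p = 0.00119; adjusted p = 0.158 with an estimated correlation). The cornified-envelope genes SPRR3 and SPRR1B rose 3.89-fold and 2.67-fold.

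Drug targets parted between the 2 classes of spots. Of 27 target genes 17 were higher in epithelial-high spots and 4 lower, or 17 and 5 adjusted over the list alone (adjusted p = 0.00395; adjusted p = 0.150 with an estimated correlation). NECTIN4, the target of enfortumab vedotin, was 4.77-fold higher (log2 2.25 ± 0.24; 187 ± 143 against 44.2 ± 35.9 CPM, SD, n = 22) and higher in 21 of 22 tumours. The receptor kinases FGFR1 and AXL were 4.37-fold and 4.06-fold lower, both in 22 of 22 tumours. Cell-cycle genes were higher for 9 of 11 (adjusted p = 0.00158; adjusted p = 0.257 with an estimated correlation), with the mitotic kinase AURKA 2.12-fold higher. Hypoxia genes were higher for 6 of 8, or 7 adjusted over the list alone (adjusted p = 0.00162; adjusted p = 0.150 with an estimated correlation), with the glucose transporter SLC2A1 2.54-fold higher. NRF2 target genes were higher for 7 of 9 (adjusted p = 0.00334; adjusted p = 0.0606 with an estimated correlation), with GCLC, an enzyme of glutathione synthesis, 2.08-fold higher.

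Every measured gene of 4 mesenchymal lists was lower in epithelial-high spots. These were 13 activated-fibroblast genes, 8 smooth-muscle genes, 10 endothelial genes and 7 genes of epithelial-mesenchymal transition (adjusted p between 1.34e-11 and 4.73e-08; adjusted p = 0.0606 for each with an estimated correlation). The fibroblast protease FAP was 6.24-fold lower (log2 -2.64 ± 0.31), the smooth-muscle gene LMOD1 8.09-fold, the endothelial adhesion gene PECAM1 4.23-fold, vimentin, VIM, 6.34-fold and the transcription factor ZEB2 3.70-fold. Of 10 inflammatory-fibroblast genes 8 were lower (adjusted p = 2.83e-07; adjusted p = 0.0606 with an estimated correlation), with the chemokine CXCL12 8.01-fold and the receptor PDGFRA 5.86-fold lower.

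Immune genes were lower in epithelial-high spots as well. All 11 T-cell genes were lower (adjusted p = 2.12e-08; adjusted p = 0.0687 with an estimated correlation), with the receptor constant gene TRAC 2.80-fold lower. All 10 cytotoxic genes were lower (adjusted p = 2.83e-07; adjusted p = 0.0606 with an estimated correlation), by less: CD8A was 1.62-fold lower (log2 -0.70 ± 0.11), at 17.5 against 28.2 CPM. Plasma-cell genes were lower for 9 of 10, or 10 adjusted over the list alone (adjusted p = 2.46e-07; adjusted p = 0.0901 with an estimated correlation), with the antibody gene IGHG1 9.11-fold lower. Macrophage genes were lower for 10 of 11 (adjusted p = 1.43e-07; adjusted p = 0.116 with an estimated correlation), with the scavenger receptor CD163 5.44-fold lower. Regulatory T-cell genes split: 5 of 6 were lower (adjusted p = 0.0460; adjusted p = 0.152 with an estimated correlation), with FOXP3 2.45-fold lower, while IKZF2 was 3.25-fold higher in epithelial-high spots.

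The smaller immune lists went the same way. Lower were 8 of 11 germinal-centre and follicular-helper genes with 1 higher (adjusted p = 0.00172; adjusted p = 0.0606 with an estimated correlation) and 9 of 12 chemokines of lymphoid structures (adjusted p = 3.38e-06; adjusted p = 0.0606 with an estimated correlation). CXCL13, the chemokine that attracts B cells, was 2.41-fold lower, in 22 of 22 tumours. Also lower were 7 of 9 checkpoint genes, with HAVCR2 2.33-fold (adjusted p = 0.000124; adjusted p = 0.0898 with an estimated correlation), and 6 of 11 lymphoid-organiser genes, with the adhesion gene VCAM1 5.40-fold (adjusted p = 0.00129; adjusted p = 0.116 with an estimated correlation). Lower were 5 of 8 dendritic-cell genes (adjusted p = 0.00528) and 3 of 3 mast-cell genes (adjusted p = 0.00615); adjusted p = 0.116 for both with an estimated correlation. Of 6 neutrophil genes 4 were lower (adjusted p = 0.0176; adjusted p = 0.150 with an estimated correlation). The lists of neuroendocrine genes (1 of 8 lower, adjusted p = 0.284), PPAR targets (4 of 8 higher, 0.149), interferon-gamma response (3 of 10 lower, 0.149), type I interferon response (1 of 8 higher, 0.475) and MHC class I presentation (1 of 6 lower, 0 adjusted over the list alone, 0.866) did not pass. The interferon-induced chemokine CXCL9 was 1.73-fold lower (log2 -0.79 ± 0.28, adjusted p = 0.0247) but higher in 7 of 22 tumours, and in the large format alone its log2 change was -0.07 (adjusted p = 0.891). The class difference itself differed between slide formats for 2 of the 17856 genes.

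**Figure D2:**
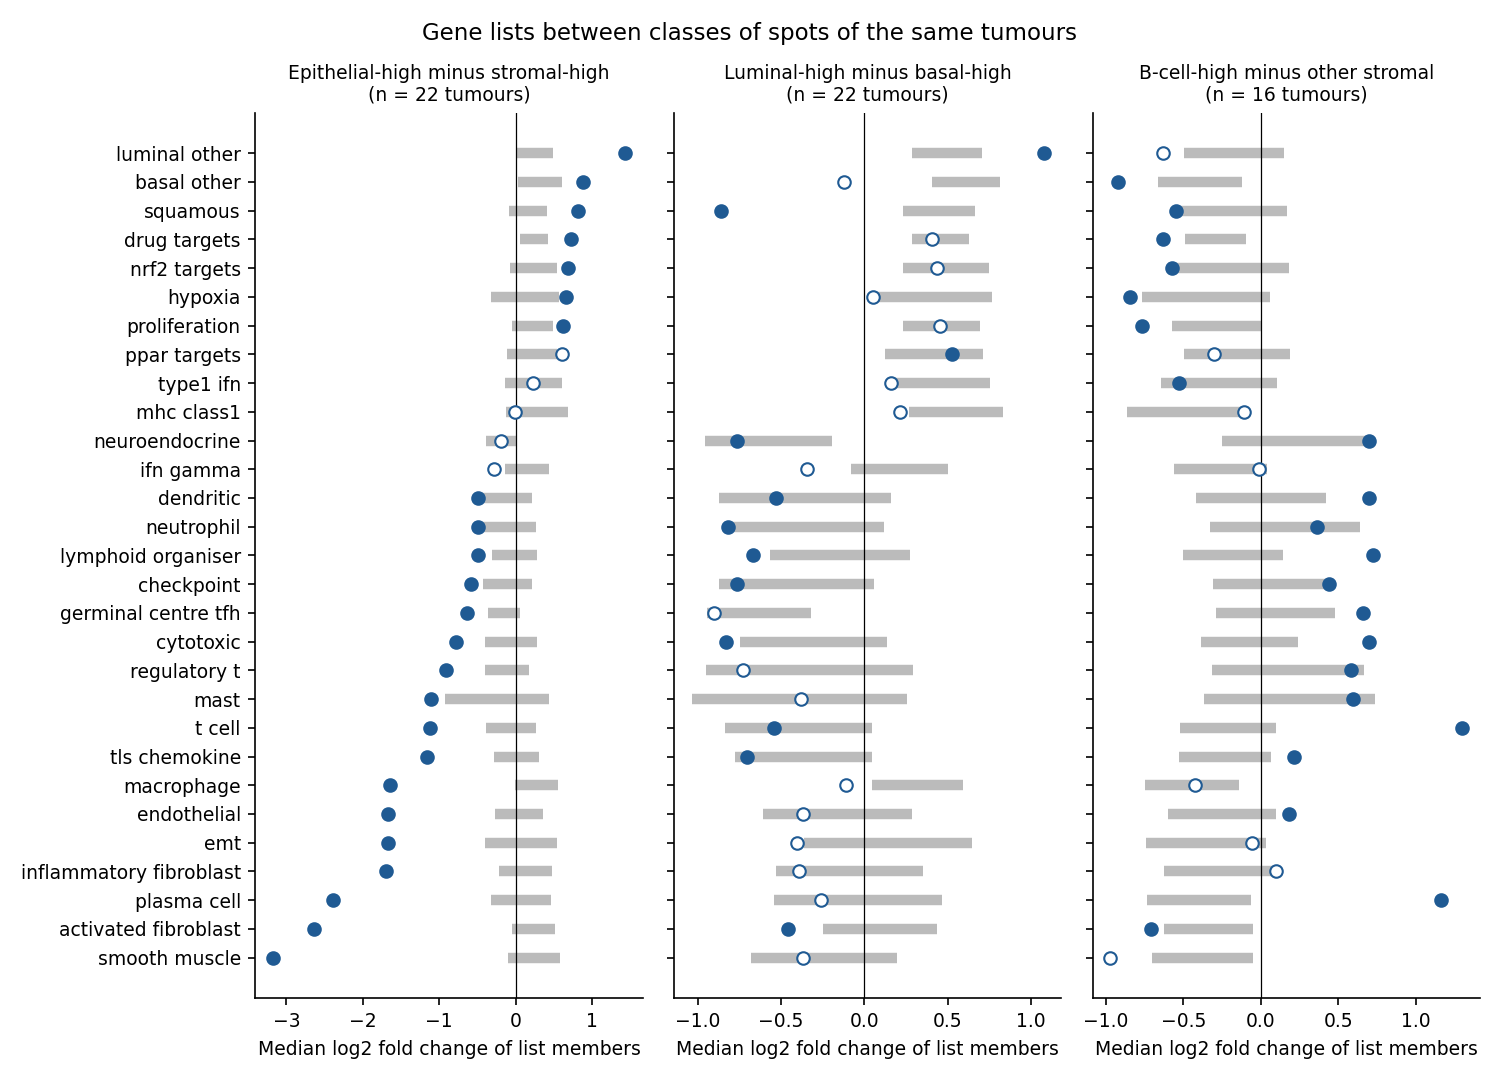
Median log2 fold change of the members of each gene list in the 3 comparisons of spot classes. Filled points passed the list test at the preset correlation, open points did not, and grey bars span the middle 95% of medians of 10000 random lists matched on expression.

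The second comparison asked which genes go with luminal and basal keratin and uroplakin programmes inside the epithelial side of a tumour. Basal-high spots are those with the lowest luminal minus basal score: in 4 of 22 tumours their median basal level was 0, and in 16 of 22 their median level of epithelial genes was below that of luminal-high spots, so in part they are spots with few luminal and epithelial UMIs. Luminal-high spots had the higher silent-gene level in 6 of 22 tumours, all of the small format. In tumour 5 it was 83.3% against 4.81% in basal-high spots, with epithelial medians of 7.77 against 29.4 UMIs per 10000. In tumour 6 the median luminal level was 0 in luminal-high and 1.13 in basal-high spots. DHRS2 was 5.16-fold higher in luminal-high spots (log2 2.37 ± 0.36, n = 22) and higher in 22 of 22 tumours. ANXA9 was 5.42-fold higher, and ADIRF (4.10-fold), PSCA (4.07-fold), the synuclein SNCG (3.94-fold) and PALM3 (3.84-fold) followed. Lower in luminal-high spots were the elastase inhibitor PI3, 3.75-fold (log2 -1.91 ± 0.34), and the airway protease TMPRSS11D, 3.21-fold (-1.68 ± 0.28). SERPINB2 (2.88-fold), the transcription factor BNC1 (2.82-fold), SLURP2 (2.76-fold) and TMPRSS11A (2.76-fold) were lower too, each in at least 19 of 22 tumours.

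Among the drug targets named in advance, ERBB2 and NECTIN4 were higher in luminal-high spots. ERBB2, which encodes HER2, was 2.70-fold higher (log2 1.43 ± 0.33, adjusted p = 0.00758; 469 ± 622 against 124 ± 82.9 CPM, SD) and higher in 20 of 22 tumours. NECTIN4 was 1.90-fold higher (0.93 ± 0.30, adjusted p = 0.0251), in 16 of 22 tumours. CD274, which encodes PD-L1, was 1.57-fold lower (-0.65 ± 0.20, adjusted p = 0.0221) and higher in 6 of 22 tumours; the silent genes moved further, by a median of -0.90, and CD274 averaged 26.6 CPM in the epithelial side, under an even share. FGFR3 (log2 0.41 ± 0.25, adjusted p = 0.156) and EGFR (0.61 ± 0.37, adjusted p = 0.152) did not pass. In the large format the log2 changes of NECTIN4 and ERBB2 were 1.67 and 2.21, and in the small format 0.37 and 0.84. The difference between formats passed for NECTIN4 (adjusted p = 0.0440) and ERBB2 (0.0489). The silent genes moved the other way, by a median of -1.85 in the large format and -0.19 in the small. The whole list of 27 targets, with 10 higher and 3 lower, did not pass (adjusted p = 0.0755).

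**Figure D3:**
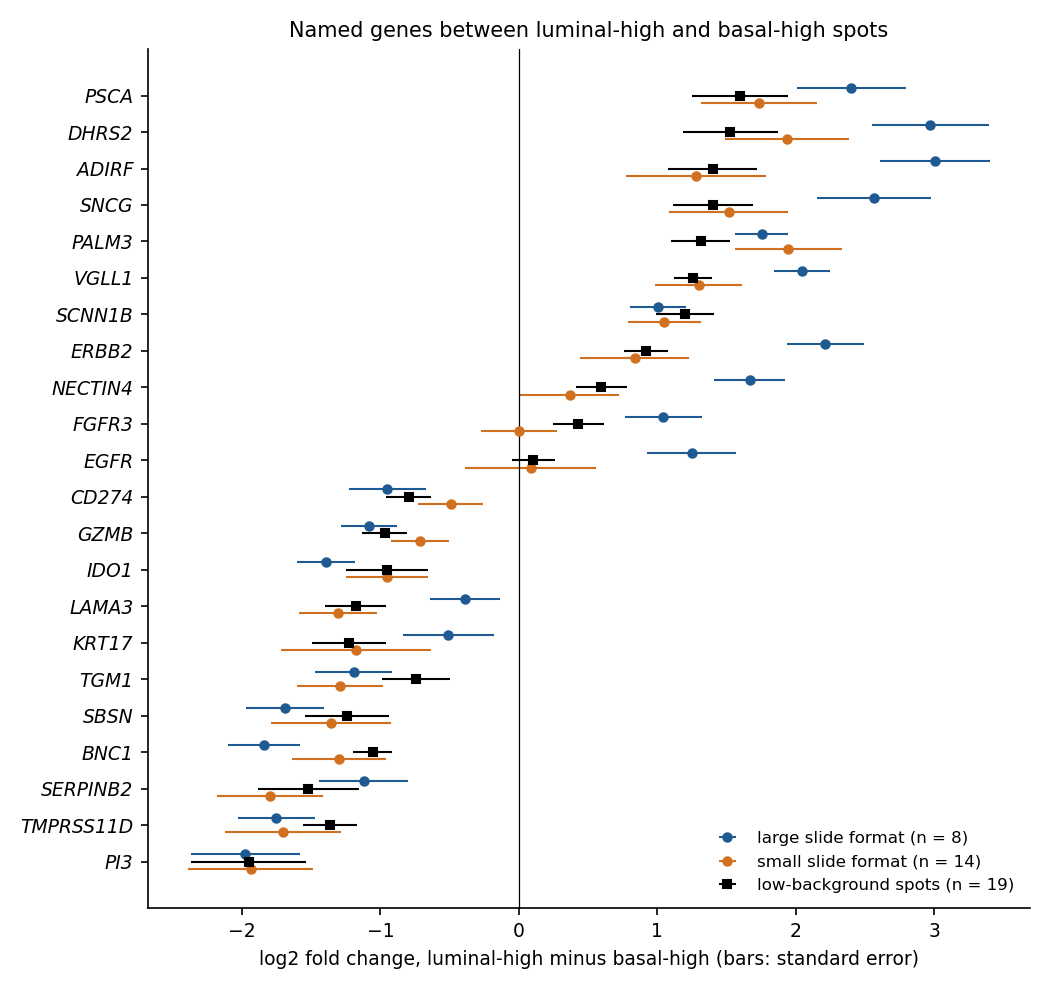
Log2 fold change of named genes between luminal-high and basal-high spots, with standard errors, fitted in the large slide format, the small slide format and low-background spots. ERBB2 and NECTIN4 had larger changes in the large format, while PI3 had -1.98, -1.94 and -1.95 in the 3 fits.

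Of 17245 genes tested, 3468 were higher in luminal-high spots and 3742 lower, over 9085 luminal-high and 10398 basal-high spots. The count differed between the tumours of the 2 slide formats, which may differ in more than the slide. In the large format 7045 genes were higher and 7181 lower of 17651, whereas in the small format edgeR called 0 of 16324, with 684 at an unadjusted p under 0.05. Over all 22 tumours DESeq2 called 3535 higher and 5874 lower, and limma on 1 ratio per tumour 2567 and 2068. The class difference itself differed between formats, with 3796 genes more positive in the large format and 3757 in the small. Silent genes were part of the shift: their level was 19.4% of an even share in luminal-high and 32.9% in basal-high spots, higher in basal-high spots in 16 of 22 tumours, with a median log2 change of -0.90, and 180 of 307 tested were called lower. In the large format the silent-gene level was 8.79% in luminal-high and 42.7% in basal-high spots. There 336 of 336 silent genes were called lower, with a median of -1.85. In the small format the level was 25.4% and 27.4%, and 0 of 233 were called lower, with a median of -0.19. The format with the many calls was thus also the one with the large silent-gene shift. In the large format the epithelial defining genes had a median of 74.0 UMIs per 10000 in luminal-high and 20.7 in basal-high spots, and in the small format 35.7 and 29.5. Depth differed as well, with medians over tumours of 3846 UMIs per spot in luminal-high and 2122 in basal-high spots. Luminal-high spots were deeper in 15 of 22 tumours, in every tumour of the large format but only in part of the small. Low-background spots of 19 tumours gave 3200 genes higher and 3323 lower, 4798 of them shared with the calls over all spots.

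Luminal genes outside the defining list rose in luminal-high spots. Of 13 tested 12 were higher (adjusted p = 3.37e-07; adjusted p = 0.261 with an estimated correlation). The transcription cofactor VGLL1 was 3.11-fold higher (log2 1.64 ± 0.24) and the sodium channel subunit SCNN1B 2.09-fold higher (1.06 ± 0.18). Of 8 PPAR target genes 4 were higher (adjusted p = 0.0246; adjusted p = 0.261 with an estimated correlation). They included ACSL5, which activates fatty acids, at 2.58-fold. In low-background spots the luminal list kept 12 of 13 genes higher (adjusted p = 3.60e-07), and the PPAR list did not pass (3 of 8 higher, adjusted p = 0.281).

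Squamous genes fell. Of 16 tested 8 were lower in luminal-high spots, or 11 adjusted over the list alone (adjusted p = 0.00079; adjusted p = 0.265 with an estimated correlation). Suprabasin, SBSN, was 2.75-fold lower (log2 -1.46 ± 0.29) and the envelope cross-linker TGM1 2.34-fold lower (-1.22 ± 0.23). Of 14 further basal genes 1 was lower, the laminin subunit LAMA3, 1.92-fold (-0.94 ± 0.24, adjusted p = 0.0119), and that list did not pass (adjusted p = 0.618). KRT17, a basal keratin, had a log2 change of -0.88 ± 0.39 (adjusted p = 0.0651). In low-background spots KRT17 was lower by -1.23 (adjusted p = 0.00213), 6 of 14 basal genes were lower, and the list passed (adjusted p = 0.0186; adjusted p = 0.391 with an estimated correlation).

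Cytotoxic, T-cell and checkpoint genes were lower in luminal-high spots, in the direction of the silent genes. The cytotoxic median lay below the middle 95% of random lists matched on expression, and the T-cell and checkpoint medians within it. Of 10 cytotoxic genes 9 were lower, or 10 adjusted over the list alone (adjusted p = 5.57e-06; adjusted p = 0.261 with an estimated correlation). Granzyme B, GZMB, had 20.3 CPM in luminal-high and 35.3 CPM in basal-high spots (log2 -0.83 ± 0.14, 1.78-fold, n = 22), and granulysin, GNLY, was 1.84-fold lower. The mean silent gene had 10.7 and 18.2 CPM in the same classes. Of 11 T-cell genes 9 were lower, or 10 adjusted over the list alone, with TRAC 1.45-fold (adjusted p = 0.000808; adjusted p = 0.261 with an estimated correlation). Of 9 checkpoint genes 8 were lower, with IDO1 2.16-fold and LAG3 1.82-fold (adjusted p = 0.000334; adjusted p = 0.261 with an estimated correlation). In low-background spots, where 39 of 73 silent genes were lower with a median of -0.59, all 10 cytotoxic and all 11 T-cell genes were lower (adjusted p = 3.60e-07 and 4.79e-06; adjusted p = 0.0966 for both with an estimated correlation).

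No list that was lower had a median past the -0.90 of the silent genes: the cytotoxic list had -0.83 and the squamous list -0.86. Of all 29 lists 1 lay above the middle 95% of matched random lists, 17 within and 11 below; the PPAR, lymphoid chemokine, dendritic, neutrophil and neuroendocrine lists were within. In low-background spots, where the silent genes had -0.59, lists past it included cytotoxic (-0.77), squamous (-0.69), T-cell (-0.74), checkpoint (-0.81), lymphoid chemokine (-0.97), lymphoid-organiser (-0.77) and activated-fibroblast genes (-0.76). Lower were 5 of 13 activated-fibroblast genes, with FAP 1.59-fold (adjusted p = 0.0392; adjusted p = 0.444 with an estimated correlation). Of 12 chemokines of lymphoid structures 6 were lower, or 8 adjusted over the list alone, with CCL4 2.03-fold (adjusted p = 0.0112; adjusted p = 0.261 with an estimated correlation). Of 11 lymphoid-organiser genes 6 were lower, or 7 adjusted over the list alone, with LTA 2.08-fold (adjusted p = 0.00998; adjusted p = 0.289 with an estimated correlation). Lower were 5 of 7 dendritic-cell genes, with CD1C 1.82-fold (adjusted p = 0.0416), and 4 of 6 neutrophil genes, or 5 adjusted over the list alone, with CXCR2 2.16-fold (adjusted p = 0.0478); adjusted p = 0.444 for both with an estimated correlation. Of 6 neuroendocrine genes 3 were lower (adjusted p = 0.0392; adjusted p = 0.474 with an estimated correlation). NEUROD1, their transcription factor, had 9.50 and 18.4 CPM, the level of the mean silent gene in each class. Lists without a call were epithelial-mesenchymal transition (2 of 7 lower, adjusted p = 0.0809), proliferation (0 of 11 past the threshold, 0.167), hypoxia (1 of 8 lower, 0 adjusted over the list alone, 0.883; median 0.05, mean -0.00), NRF2 targets (3 higher and 2 lower of 9, 0.561) and inflammatory fibroblasts (4 of 10 lower, 0.181). Smooth muscle (0 of 8, 0.167), endothelium (3 of 9 lower, 0.143), regulatory T cells (4 lower and 1 higher of 5, 0.115), germinal centre (5 lower and 1 higher of 11, or 7 and 1 adjusted over the list alone, 0.115) and plasma cells (1 of 10 lower, 0 adjusted over the list alone, 0.194) did not pass either. Nor did macrophages (0 of 11, 0.618), mast cells (0 of 3, 0.298), interferon gamma (4 of 10 lower, 0.120), type I interferon (1 of 8 lower, 0 adjusted over the list alone, 0.883) and MHC class I (0 of 6, 0.423).

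The third comparison asked what surrounds B cells in the stroma, since the series addresses lymphoid structures. CCL19, the chemokine that draws T cells and dendritic cells into lymph nodes, was 4.84-fold higher in B-cell-high spots (log2 2.27 ± 0.34, n = 16 tumours). CXCL13 was 4.79-fold higher (2.26 ± 0.42), at 265 ± 556 against 32.9 ± 31.7 CPM (SD). The B-lineage genes SPIB (4.80-fold), TNFRSF13B (4.77-fold), FCRL1 (4.41-fold) and NIBAN3 (4.22-fold) were higher in at least 13 of 16 tumours. Lower were SERINC2 4.04-fold (log2 -2.01 ± 0.31), KRT17 3.81-fold, the tetraspanin CD9 3.77-fold, the S-phase kinase TK1 3.54-fold, FXYD3 3.51-fold and EGFR 3.47-fold. CD9, TK1 and EGFR were lower in 16 of 16 tumours.

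Of 13481 genes tested, 807 were higher in B-cell-high spots and 1912 lower, over 864 B-cell-high and 30318 other spots. The balance moved with the scaling: library size alone gave 1197 higher and 650 lower and a median change of all genes of 0.16 against -0.09 with TMM, and DESeq2 gave 1233 and 1376. Silent genes were higher in B-cell-high spots, at a mean of 21.1 against 12.2 CPM, in 12 of 16 tumours. In 2 of these tumours their level in B-cell-high spots was over 80% of an even share, near the level of background alone. Of 57 tested 19 were called higher, with a median log2 change of 0.85; without the count filter the median of all 348 was 0.63. Over the called genes the fold change fell with expression (rho = -0.468). Low-background spots of 7 tumours gave 529 genes higher and 993 lower, 1143 of them shared with the calls over all spots.

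T-cell and plasma-cell genes rose in B-cell-high spots, with list medians above the 0.85 of the silent genes (1.17 for plasma cells), while the cytotoxic and lymphoid-organiser medians of 0.70 and 0.72 lay below it and above the 0.63 of all silent genes. All 11 T-cell genes were higher (adjusted p = 1.31e-13; adjusted p = 0.0464 with an estimated correlation). CD3E was 2.64-fold higher, in 16 of 16 tumours, and TRBC1 2.65-fold. Of 9 cytotoxic genes 7 were higher, or 9 adjusted over the list alone (adjusted p = 3.97e-09; adjusted p = 0.0464 with an estimated correlation). GZMK, the granzyme of memory T cells, rose 2.36-fold (log2 1.24 ± 0.26) and CD8A 1.63-fold (0.71 ± 0.21, adjusted p = 0.0184). Of 10 plasma-cell genes 8 were higher, or 9 adjusted over the list alone, with IGHM 3.77-fold and POU2AF1 3.46-fold (adjusted p = 2.00e-11; adjusted p = 0.0464 with an estimated correlation). Of 10 lymphoid-organiser genes 5 were higher, or 8 adjusted over the list alone (adjusted p = 6.36e-07; adjusted p = 0.0464 with an estimated correlation). These included the homing receptor CCR7 (2.86-fold) and lymphotoxin beta, LTB (3.59-fold). In low-background spots all 11 T-cell genes were higher with a median of 1.81 (adjusted p = 2.35e-17; adjusted p = 0.120 with an estimated correlation), against 0.52 for the silent genes, 1.15 for the cytotoxic list and 0.78 for the lymphoid-organiser list.

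Germinal-centre, dendritic-cell, checkpoint and lymphoid chemokine lists passed with medians of 0.66, 0.70, 0.44 and 0.22, below the 0.85 of the silent genes tested; the first 2 lay above the 0.63 of all silent genes. In low-background spots the medians of the 4 lists were 0.99, 1.14, 0.86 and 0.73, above the 0.52 of the silent genes. Of 9 germinal-centre genes 3 were higher, or 4 adjusted over the list alone (adjusted p = 0.000338; adjusted p = 0.0661 with an estimated correlation). With CXCL13 they were CXCR5, its receptor (3.16-fold), and SH2D1A, an adaptor of follicular helper T cells (2.87-fold). Of 7 dendritic-cell genes 4 were higher, or 5 adjusted over the list alone, with CD1C 2.68-fold and IRF8 2.24-fold (adjusted p = 0.000561; adjusted p = 0.113 with an estimated correlation). LAMP3, a marker of mature dendritic cells, was 1.65-fold higher (log2 0.73 ± 0.22, adjusted p = 0.0223). CCL21, the other ligand of CCR7, had a log2 change of 0.83 ± 0.33 (adjusted p = 0.0713). Of 8 checkpoint genes 2 were higher, or 4 adjusted over the list alone, with TIGIT 2.39-fold (adjusted p = 0.00157; adjusted p = 0.174 with an estimated correlation). Of 11 lymphoid chemokines 2 were higher and 1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.0165; adjusted p = 0.213 with an estimated correlation).

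Further lists passed upward with medians below the 0.85 of the silent genes tested. In low-background spots regulatory T cells (0.78) and mast cells (0.63) lay above the 0.52 of the silent genes, and the others below it. The lists were endothelium (1 higher and 1 lower of 9, or 2 and 1 adjusted over the list alone, adjusted p = 0.0390; adjusted p = 0.234 with an estimated correlation), with the venule receptor ACKR1 2.03-fold higher, and mast cells (0 of 3, or 2 adjusted over the list alone, adjusted p = 0.0474; adjusted p = 0.234 with an estimated correlation). Others were regulatory T cells (1 of 5 higher, adjusted p = 0.00849; adjusted p = 0.0653 with an estimated correlation), neutrophils (1 of 5 higher, adjusted p = 0.0267; adjusted p = 0.178 with an estimated correlation) and neuroendocrine genes (1 of 4 higher, or 2 adjusted over the list alone, adjusted p = 0.0207; adjusted p = 0.194 with an estimated correlation).

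Basal genes and drug targets fell in B-cell-high spots. These spots also had fewer epithelial UMIs, with a median of 3.66 per 10000 against 7.39 in other spots, or 3.78 against 17.4 in the small format and 3.65 against 3.66 in the large. Lower were 11 of 14 basal genes (adjusted p = 2.02e-05; adjusted p = 0.0653 with an estimated correlation) and 11 of 23 drug targets, or 15 adjusted over the list alone (adjusted p = 0.000182; adjusted p = 0.0464 with an estimated correlation). Cell-cycle genes were lower for 7 of 9, with CCNB1 2.04-fold (adjusted p = 0.00174; adjusted p = 0.194 with an estimated correlation), and hypoxia genes for 4 of 6, or 5 adjusted over the list alone, with VEGFA 2.07-fold (adjusted p = 0.00474; adjusted p = 0.178 with an estimated correlation). NRF2 targets were lower for 3 of 6, with NQO1 2.13-fold (adjusted p = 0.0441; adjusted p = 0.118 with an estimated correlation). Squamous genes were lower for 2 of 9 (adjusted p = 0.0474, or 0.234 with an estimated correlation). Type I interferon genes were lower for 3 of 8, or 4 adjusted over the list alone, with IFI6 2.51-fold. That list had adjusted p = 0.0378, or 0.234 with an estimated correlation. In low-background spots 0 of 8 type I interferon genes were lower, at a median of -0.17 against -0.53. There the list did not pass the list test (adjusted p = 0.810). Activated-fibroblast genes were lower for 5 of 13, or 8 adjusted over the list alone, with the protease MMP11 2.80-fold (adjusted p = 0.0362; adjusted p = 0.341 with an estimated correlation), but in low-background spots of 7 tumours 0 of 13 were and the list did not pass (adjusted p = 0.408), at a median of -0.54 against -0.71 over the 16 tumours. Further luminal genes (5 of 11 lower, or 6 adjusted over the list alone, adjusted p = 0.0558) did not pass as a list, with ERBB2 3.32-fold lower. Nor did smooth muscle (1 of 8 lower, or 7 adjusted over the list alone, 0.0728), macrophages (2 of 11 lower, or 1 adjusted over the list alone, 0.0953), PPAR targets (2 of 8 lower, or 3 adjusted over the list alone, 0.213) and inflammatory fibroblasts (2 of 10 higher, 0.151). Median, mean and test differed in sign for epithelial-mesenchymal transition (1 of 6 lower, 0.594; median -0.06, mean -0.27, test upward), interferon gamma (1 of 10 higher, 0.141; median -0.01, mean 0.11, test upward) and MHC class I (0 of 6, 0.251; median -0.11, mean -0.00, test upward). In low-background spots of 7 tumours macrophages (median 0.17, adjusted p = 0.0386) and inflammatory fibroblasts (0.19, 0.0190) passed the list test upward. So did interferon gamma (0.44, 5.69e-05) and MHC class I (0.31, 0.000673). Their medians lay below the 0.52 of the silent genes there, and with an estimated correlation each adjusted p was at least 0.201. CIITA, the regulator of MHC class II genes, was 2.03-fold higher (log2 1.02 ± 0.27) over all spots. The class difference was more positive in the large slide format for 4 of the 13481 genes and in the small format for 1.

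T-cell, cytotoxic and lymphoid-organiser genes were also higher in the spots next to B-cell-high spots. At 1 step, summed T-cell UMIs were higher by 1.19 ± 0.70 on the log2 scale (SD, n = 16, adjusted p = 0.000183) than at 6 or more steps in the same tumour, at 863 against 403 CPM. The values fell with distance, to 0.73 at 2 steps and 0.58 at 3 steps. Cytotoxic genes were higher by 0.98 ± 0.62 at 1 step and by 0.71 and 0.51 at 2 and 3 steps, and lymphoid-organiser genes by 0.96 ± 0.50, 0.70 and 0.48. At 1 step all 3 lists were higher in 16 of 16 tumours (adjusted p = 0.000183 for each), 2 of them with a silent-gene level over 80% at 1 step. Plasma-cell genes were higher by 1.28 ± 1.83 at 1 step (adjusted p = 0.0290, 12 of 16 tumours) and 0.94 at 2 steps (adjusted p = 0.0467), and at 3 steps the value was 0.76 (adjusted p = 0.0703). With the reference at 4 or more steps plasma cells did not pass at 1 step (adjusted p = 0.0529) or 2 steps (0.0881). Mast-cell genes were higher by 1.13 ± 0.92, 1.01 and 0.57, and germinal-centre genes by 0.69 ± 0.64, 0.55 and 0.44, each in at least 12 of 16 tumours.

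Structural lists did not pass at any distance. At 1 step the log2 differences were -0.48 ± 0.93 for activated fibroblasts (adjusted p = 0.0790), 0.25 ± 0.50 for endothelium (0.0915), -0.39 ± 1.83 for smooth muscle (0.478) and -0.14 ± 0.85 for macrophages (0.569). In all, 17 of 30 values passed the exact sign-flip permutation test. The silent-gene level had medians of 29.4%, 26.4% and 26.2% at 1, 2 and 3 steps against 10.4% at 6 or more, higher in 13 of 16 tumours at each distance. Tested as differences of CPM in place of log2, 18 of 30 values passed, and with the silent-gene level subtracted from the CPM 9 did. At 1 step T-cell, cytotoxic and lymphoid-organiser genes were then higher in 14, 14 and 13 of 16 tumours, and the T-cell difference was 352 ± 436 CPM (SD, adjusted p = 0.0224). T-cell genes no longer passed at 2 steps (adjusted p = 0.114) or 3 steps (0.0921), nor cytotoxic genes at 3 steps (0.0887); as CPM with nothing subtracted they had 0.000183, 0.000687 and 0.000262. At 1 step the germinal-centre difference was 20.3 ± 105 (adjusted p = 0.578) and the mast-cell difference 16.7 ± 51.9 (adjusted p = 0.316).

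**Figure D4:**
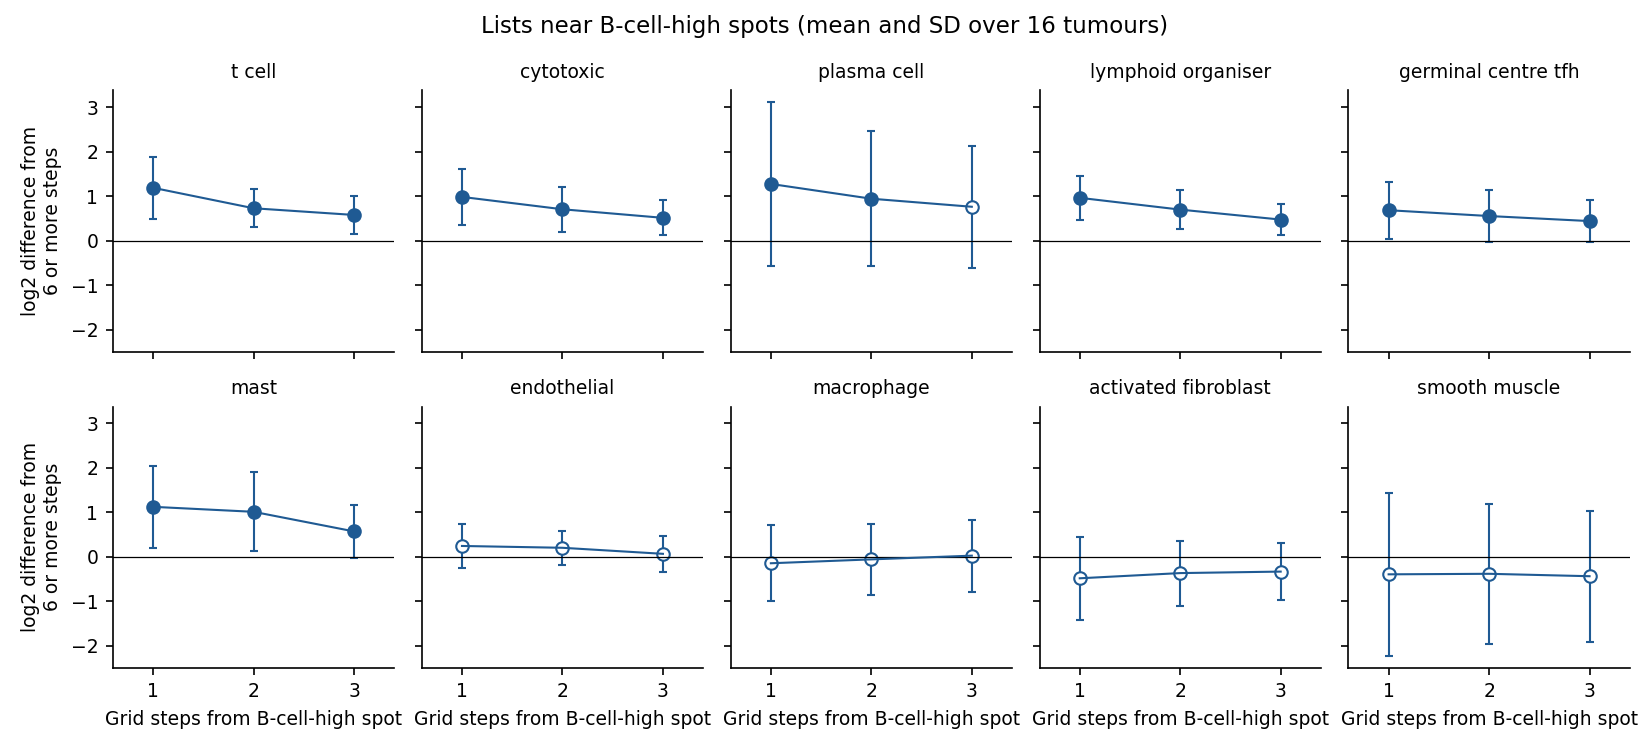
Log2 difference of summed list CPM at 1, 2 and 3 grid steps from a B-cell-high spot against 6 or more steps, as mean and SD over 16 tumours. Filled points passed the exact permutation test after adjustment; T-cell genes fell from 1.19 at 1 step to 0.58 at 3 steps.

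Across tumours, 3 of 16 planned pairs of measures were correlated. Tumours with higher basal keratin and desmosomal genes in their epithelial side had higher squamous genes there: r = 0.903 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 0.00016) and rho = 0.813 (p = 2e-05, adjusted p = 0.00016; n = 22). Without the 2 tumours farthest from the median r was 0.872, and it was 0.974 in the large format (n = 8, exact permutation p = 0.000174) and 0.886 in the small format (n = 14, permutation p = 0.0001). Tumours with more epithelial expression had less cytotoxic expression, with r = -0.648 (p = 0.00193, adjusted p = 0.0103) and rho = -0.815 (p = 1e-05, adjusted p = 0.00016). Without the 2 farthest tumours r was -0.616, and it was -0.896 in the large and -0.646 in the small format; in low-background spots r was -0.560 (adjusted p = 0.0898, n = 20) and rho -0.675 (adjusted p = 0.0119). Ranks adjusted for background gave r = -0.759 (adjusted p = 0.00032). With lists as the log2 of summed CPM r was -0.417 (adjusted p = 0.145) and rho -0.691 (adjusted p = 0.00315). Both measures were CPM of the same sums over all spots of a section. A larger share of epithelial UMIs leaves a smaller share for other genes, so the measures were not independent. The epithelial list itself fell with the silent-gene level of the tumour (rho = -0.565, adjusted p = 0.0264), as did activated fibroblasts (rho = -0.578, adjusted p = 0.0259).

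The B-cell list was correlated with CXCL13, with r = 0.645 (p = 0.00099, adjusted p = 0.00792) and rho = 0.530 (p = 0.0130, adjusted p = 0.0526). Without the 2 farthest tumours r was 0.419 (permutation p = 0.0670), and it was 0.144 in the large format (exact permutation p = 0.711) and 0.746 in the small format (permutation p = 0.00233). The B-cell list also followed the silent-gene level of the tumour (rho = 0.886, adjusted p = 0.00018), as did NECTIN4 in the epithelial side in the other direction (rho = -0.637, adjusted p = 0.0109) and EGFR (rho = -0.666, adjusted p = 0.00873). The B-cell and T-cell lists had r = 0.518 (adjusted p = 0.0546). The luminal and basal lists had r = -0.452 (adjusted p = 0.115), and the basal list and EGFR r = 0.254 (adjusted p = 0.450). Another 9 pairs had adjusted p between 0.269 and 0.874 for r. They paired the luminal list with NECTIN4, ERBB2, FGFR3 and the cytotoxic list, the basal list with CD274, the B-cell list with plasma cells, and the cytotoxic list with CD274, interferon gamma and activated fibroblasts.

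**Figure D5:**
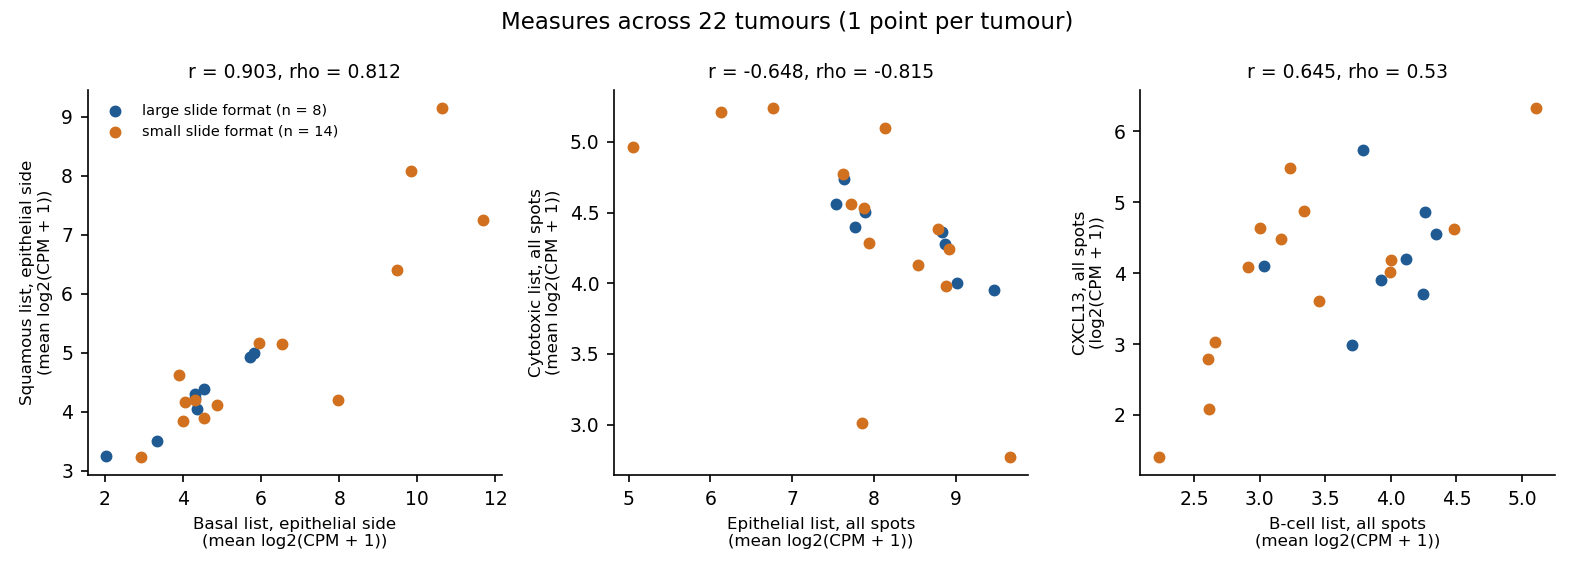
Mean log2(CPM + 1) of list members, or of CXCL13, in each of 22 tumours, with 1 point per tumour coloured by slide format. The basal and squamous lists rose together in both formats, and the B-cell list and CXCL13 had r = 0.144 in the large format (n = 8) and 0.746 in the small (n = 14).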

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

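Most named genes kept their direction and their side of the threshold under the settings fixed in advance: 466 of 475 values in the epithelial against stromal comparison, 340 of 421 in the luminal against basal and 353 of 418 in the B-cell comparison. The others lost the call (9, 71 and 59), gained it (0, 8 and 6) or reversed (0, 2 and 0). For distance 81 of 88 values and for 8 of the 16 correlations 51 of 64 stayed the same. Settings on low-background spots, the slide formats in the distance analysis, CPM in place of log2, and the subtraction of the silent-gene level were chosen after seeing the data. Spots thinned to 500 UMIs gave no value for the B-cell comparison, since no tumour then had 20 B-cell-high spots. Depth limits the shallow tumours, and 1.5-fold changes were recovered for 10.1% and 9.46% of simulated genes in the luminal against basal and B-cell comparisons. Where no cause is named below, the cause was not tested.

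Epithelial-high against stromal-high spots gave 975 genes higher and 1389 lower without the tumour block, 1473 and 1880 in the small slide format, and 1381 and 1387 with spots thinned to 500 UMIs, where fewer genes were tested. Low-background spots of the small format gave 1898 higher. CXCL9 was reversed in low-background spots of the large format (log2 0.14, adjusted p = 0.816).

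Luminal-high against basal-high spots gave 2233 genes higher with library size only and a median change of all genes of -0.20. There were 41 higher and 13 lower without the block, 7045 and 7181 in the large format, 0 and 0 in the small format, and 8 and 28 in low-background spots of the small format. Thinned spots gave 38 and 46, where 4235 genes were tested, and classes of 10% gave 990 and 1347, where 12005 were tested. DESeq2 gave 5874 lower and limma on 1 ratio per tumour 2068 lower. EGFR was reversed without the block (log2 -0.0536), in low-background spots of the small format (-0.13) and in thinned spots (-0.0485), and passed in none of them.

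B-cell-high against other stromal spots gave 1233 genes higher with DESeq2 and 650 lower with library size only. There were 101 higher and 41 lower without the block, 394 and 397 in the small format, and 1123 lower in the large format. Limma on 1 ratio per tumour gave 70 and 53, with a median change of all genes of -0.35. Low-background spots gave 529 and 993 (7 tumours), 326 and 289 in the large format (4 tumours) and 145 and 58 in the small (3 tumours). Classes of 20% gave 427 and 1274, and all spots in place of the stromal side 3531 and 5335.

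As differences of CPM in place of log2, 18 of the 30 distance values passed, and 9 with the silent-gene level subtracted from the CPM as well. At 1 step, macrophage genes were reversed in low-background spots (log2 0.40) and in the large format (0.0948), and smooth-muscle genes with all spots (0.0239) and in the small format (0.49); none of these values passed. Of the 16 correlations, 6 passed with means over spots and 1 in low-background spots. In the large format 8 of the 16 correlations changed sign: luminal with basal (r = 0.341), luminal with ERBB2 (-0.291), basal with EGFR (-0.677), cytotoxic with interferon gamma (-0.215), luminal with NECTIN4 (-0.404), B cells with plasma cells (-0.420), activated fibroblasts with cytotoxic (-0.255) and luminal with cytotoxic (0.140). Without the 2 farthest tumours basal with EGFR (-0.143), activated fibroblasts with cytotoxic (-0.100) and basal with CD274 (-0.00289) were reversed. Basal with CD274 was also reversed in the small format (-0.138), over all spots in place of the epithelial side (-0.0483) and with a pseudocount of 10 (-0.00942), and cytotoxic with CD274 with that pseudocount (-0.0396). Library size only reversed luminal with cytotoxic (0.0763), and summed CPM luminal with FGFR3 (-0.0356) and B cells with plasma cells (-0.0181). None of these passed.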

Other observations

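Antibody and kinase targets varied widely between tumours in the epithelial side. NECTIN4 had a mean of 158 ± 120 CPM (SD, n = 22), ERBB2 302 ± 337, FGFR3 243 ± 243 and EGFR 717 ± 1709. CEACAM6 had 95.5 ± 200 CPM. MSLN and FOLR1, with 13.1 ± 17.6 and 11.2 ± 10.8 CPM, lay below an even share of the UMIs (55.3 CPM). Of the lineage genes, KRT5 had a mean of 3661 ± 8120 CPM and a median of 143, KRT14 1562 ± 3873 and 30.6, and KRT20 230 ± 408 and 50.7. GATA3 had 730 ± 1032 and PPARG 814 ± 2066 CPM.

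The 3 tests that exchange the classes within tumours were written before the results were seen, and all other tests named below after. No biological explanation was tested. Of 40 exchanges, the real one included, 1 called as many genes for epithelial-high against stromal-high spots (7894, and 0 in the next). For B-cell-high against other spots it was also 1 (2719, and 6 in the next). In all 3 comparisons the classes were made from the same counts. Genes that go with a score then differ the same way across tumours, and an exchange tends to cancel them. That the real classes called the most genes was thus close to fixed in advance, and it decides nothing.

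The luminal against basal contrast was weighed against background and slide format. Of 40 exchanges, 1 called as many genes as the real classes (7210), but another called 6479, which points to a structure of the samples. That exchange swapped the classes in 8 of 14 tumours of the small format and in 0 of 8 of the large. Background could account for much of the count: over the called genes the fold change rose with expression (rho = 0.811; 0.680 in low-background spots), as it would if background lifted low genes in basal-high spots. In low-background spots 1 of 29 lists, the luminal genes (median 0.97), lay above the middle 95% of matched random lists. Luminal-high spots were chosen by other luminal genes, so this list would rise wherever luminal genes go together. Background alone is less likely for it, but the rise is no independent result. Below the range lay 19 lists (over all spots 1 above and 11 below). Lying there thus sets neither squamous (-0.69) nor cytotoxic genes (-0.77) apart, and background stays open for both.

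The gradient around B-cell-high spots was weighed against background and RNA spread. With the silent-gene level subtracted, 4 of 4 lists (T-cell, cytotoxic, plasma-cell and lymphoid-organiser) remained higher at 1 step. The T-cell difference fell from 459 to 352 CPM and the cytotoxic difference from 211 to 113 CPM. The subtraction took the mean level of the olfactory receptor genes off every list gene. If the list genes carry that level, background alone is unlikely for the 4 lists. Whether they do was not tested. For germinal-centre and mast-cell genes at most 30.0% of the difference was left and neither passed, so background could account for these. RNA spreading from B-cell-high spots would leave all lists the same share of their excess, and of 6 pairs of lists 1 differed: cytotoxic genes kept a median of 69.0% and lymphoid-organiser genes 41.1% in 12 tumours (adjusted p = 0.0117). The 5 pairs with T-cell or plasma-cell genes had adjusted p between 0.120 and 0.533, so spread stays open for those and may add to each list.

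The correlation of the B-cell list with CXCL13 was weighed against background that differs between tumours. In low-background spots r was 0.241 (n = 20, adjusted p = 0.489 for r), while ranks adjusted for background gave 0.503 (adjusted p = 0.0680). The tests point to different answers, so background could be the cause and the question stays open.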
